A study of Mus musculus with 14 samples.

How the data were processed

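Bulk poly(A) RNA sequencing was done on 14 libraries of mouse naive CD8+ T cells. Cells came from mice with loxP-flanked Atf4 alleles that also carry Cd4-Cre, which deletes the floxed segment during T cell development (KO below), and from mice with the floxed alleles alone (WT). No group carries Cre without the floxed alleles. Effects of Cre itself therefore cannot be told apart from those of Atf4 loss in any KO against WT comparison. They were activated in culture with antibodies against CD3 and CD28 and collected at 0, 12, 24 and 48 h. Each genotype has 1 library at 0 h and 2 libraries at each of 12, 24 and 48 h. The labels do not say whether the libraries of a group come from separate mice, cultures or days.

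The authors deposited FPKM (mapped fragments scaled by transcript length and library size) for each gene symbol and library, in 2 tables. The first holds 21878 genes in the 10 libraries of 0, 12 and 24 h. The second holds 41079 genes, noncoding ones included, in the 4 libraries of 48 h. Per the labels, the authors' processing notes name HISAT2, Bowtie2 and the genome build GRCm38. Their versions, the counting program and the gene annotation are not given in the sources used here. The tables share 18708 symbols and differ in gene set and scale, so no value of 48 h was tested against an earlier time point. Every deposited column was used. The numbers in the column names (2 and 3 at 12 and 24 h, 1 and 2 at 48 h) could not be tied to the replicate numbers of the labels, and libraries are named here by the column numbers.

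Values were taken as log2(FPKM + 1) with no further scaling. Fold changes are on that scale, which understates changes of genes with few FPKM. Genes whose highest group mean was at least 1 FPKM were tested with limma 3.58.1 in R 4.3.3, with a variance trend, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene rose, fell or changed when its adjusted p was under 0.05. The 10 libraries of the first table were fitted together, which leaves 4 residual degrees of freedom, and the 48 h libraries alone, which leaves 2. The comparisons were KO against WT at 12, 24 and 48 h, 24 h against 12 h and 12 h against 0 h in each genotype, and the change of the KO against WT difference from 12 to 24 h. At 0 h, with 1 library per genotype, no test between genotypes was made. The 12 h against 0 h tests assume that the lone 0 h library varies like the other groups. P-values measure only the spread between these libraries.

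A set of 30 gene lists, written before the data were examined, was tested: 20 pathway lists and 10 lists of cell-type, and sex-linked markers. The pathway lists are amino acid and one-carbon synthesis enzymes, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, integrated stress response regulators, ER chaperones and folding, S phase and DNA replication, G2 and mitosis, G1 cyclins with kinases and inhibitors, T cell activation markers, naive and quiescence genes, cytotoxic effector genes, inhibitory receptors, glycolysis, oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis, interferon-stimulated genes, p53 targets, glutathione and oxidative stress defence, and the BCL2 family. The marker lists are CD8 T cells, CD4 T cells, B cells, myeloid cells, dendritic cells, NK cells, γδ T cells, erythrocytes, stroma and endothelium, and sex-linked genes. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 60 tests of 20 lists at 3 times, with separate families for markers and for time comparisons. Each was also run by camera with an estimated correlation. At 0 h, a list's median difference was placed among 10000 random lists matched for expression in 20 bins. Each list also has a count of changed genes adjusted over the list alone.

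Genes were named by a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls between genotypes and the 5 largest each way in other comparisons, among genes with at least 5 FPKM in the higher group whose libraries did not overlap between groups. It adds up to 4 changed members of each list, or the member with the largest change where none passed. Predicted gene models and receptor variable segments are not named. At 0 h the 8 largest differences each way with at least 5 FPKM in 1 library are named. Symbols follow the table of each time point, so Cars, Aars and Yars at 12 and 24 h are Cars1, Aars1 and Yars1 at 48 h. Coordinates are those of the GENCODE annotation of GRCm38.

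The files give no read counts. The depth of each library relative to the first of its table was estimated from the step between the FPKM values of lowly expressed genes, which are whole multiples of 1 read for a gene's length. The depth in reads was then set for each table from the pile-up of genes with 1 read, with exon lengths of the GENCODE annotation. It assumes that these lengths are like those the authors used. The tests were checked on simulated data with 200 changed genes among 10746 (11902 at 48 h). They recovered between 70.1% and 92.5% of genes changed by 1 on the log2 scale, and between 28.4% and 59.7% of those changed by 0.5. Unchanged genes made up between 1.1% (24 h against 12 h in KO) and 5.8% (KO against WT at 12 h) of the calls. The simulation gave each gene 1 spread for all groups. It could not show effects of an unequal spread between groups. Its noise was independent between genes, so it could not show effects that many genes of a library share. It also held far fewer changed genes than the 3891 called between genotypes at 24 h and the 5845 at 48 h. Its rates may not carry over to these comparisons.

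The alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, median-of-ratios size factors, quantile normalisation, robust variance moderation, each library left out in turn, and only the 4 libraries of a time point. A replicate block by column number, protein-coding genes rescaled to the same total at 48 h, and Atf4 with its neighbours left out were chosen after seeing the data. A replicate block by the labels' numbers and a count test on recovered reads had also been planned and were not run.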

Results

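Gene expression was measured over the first 48 h of activation of naive CD8+ T cells with and without ATF4, a transcription factor that activates genes of amino acid supply and of the response to cellular stress. There were 2 libraries per genotype at 12, 24 and 48 h and 1 per genotype at 0 h. The estimated depth, in M reads, was 13 for WT and 11.7 for KO at 0 h. At 12 h it was 17.5 and 19.5 for WT libraries 2 and 3, and 16.1 and 19.1 for KO libraries 2 and 3. At 24 h it was 18.8 and 15.7 for WT libraries 2 and 3, and 16.1 and 16.3 for KO libraries 2 and 3. At 48 h it was 34.4 and 48.2 for WT libraries 1 and 2, and 40.6 and 34.6 for KO libraries 1 and 2. Between 13443 and 13827 genes were above 0 per library at 0 to 24 h and between 19547 and 24043 at 48 h. The log2 values of the libraries of a group correlated across genes with r between 0.986 and 0.996. Below, ± is the SD over n = 2 libraries unless an SE is named.

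Atf4 was the gene with the largest fall in KO at every time. Its level was 139 FPKM in the WT library and 3.59 in the KO library at 0 h. At 12 h the WT libraries 2 and 3 had 169.6 and 161.3 FPKM and the KO libraries 2 and 3 had 2.36 and 2.81. At 24 h the WT libraries 2 and 3 had 123.4 and 128.8 FPKM and the KO libraries 2 and 3 had 1.83 and 3.0. At 48 h the WT libraries 1 and 2 had 216 and 246 FPKM and the KO libraries 1 and 2 had 4.51 and 4.66. The log2 fold change of Atf4 was -5.54 (SE 0.149, adjusted p = 3.05e-06) at 12 h, -5.24 (adjusted p = 4.69e-06) at 24 h and -5.38 (SE 0.084, adjusted p = 4.49e-06) at 48 h. At 0 h Atf4 was 30.4-fold lower in KO.

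Besides Atf4, 2 of its neighbours on chromosome 15 changed at 12, 24 and 48 h. Cacna1i, which encodes a T-type calcium channel, rose from 0.0507 ± 0.00384 FPKM in WT to 12.5 ± 0.882 in KO at 12 h, 12.9-fold on the scale of log2(FPKM + 1) (adjusted p = 3.05e-06). The rise of Cacna1i was 15.5-fold at 24 h (adjusted p = 1.85e-06) and 19.8-fold at 48 h (adjusted p = 6.86e-05). Rps19bp1, which encodes a ribosomal protein S19 binding protein, fell from 42.9 ± 1.495 to 15.3 ± 0.544 FPKM at 12 h (adjusted p = 0.00895), and also fell at 24 h (log2 -1.77, adjusted p = 0.000322) and at 48 h (log2 -1.48, adjusted p = 0.00108). At 0 h the log2 difference of Rps19bp1 was -0.41 and that of Cacna1i 3.67. In GRCm38, Atf4 spans 80255184 to 80257541, Rps19bp1 80260615 to 80264315 on the opposite strand, and Cacna1i 80287238 to 80398279, which begins 29697 bases past the end of Atf4. The other tested genes within 150 kb, Syngr1, Tab1 and Mief1, did not pass at any of these times.

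**Figure D1:**
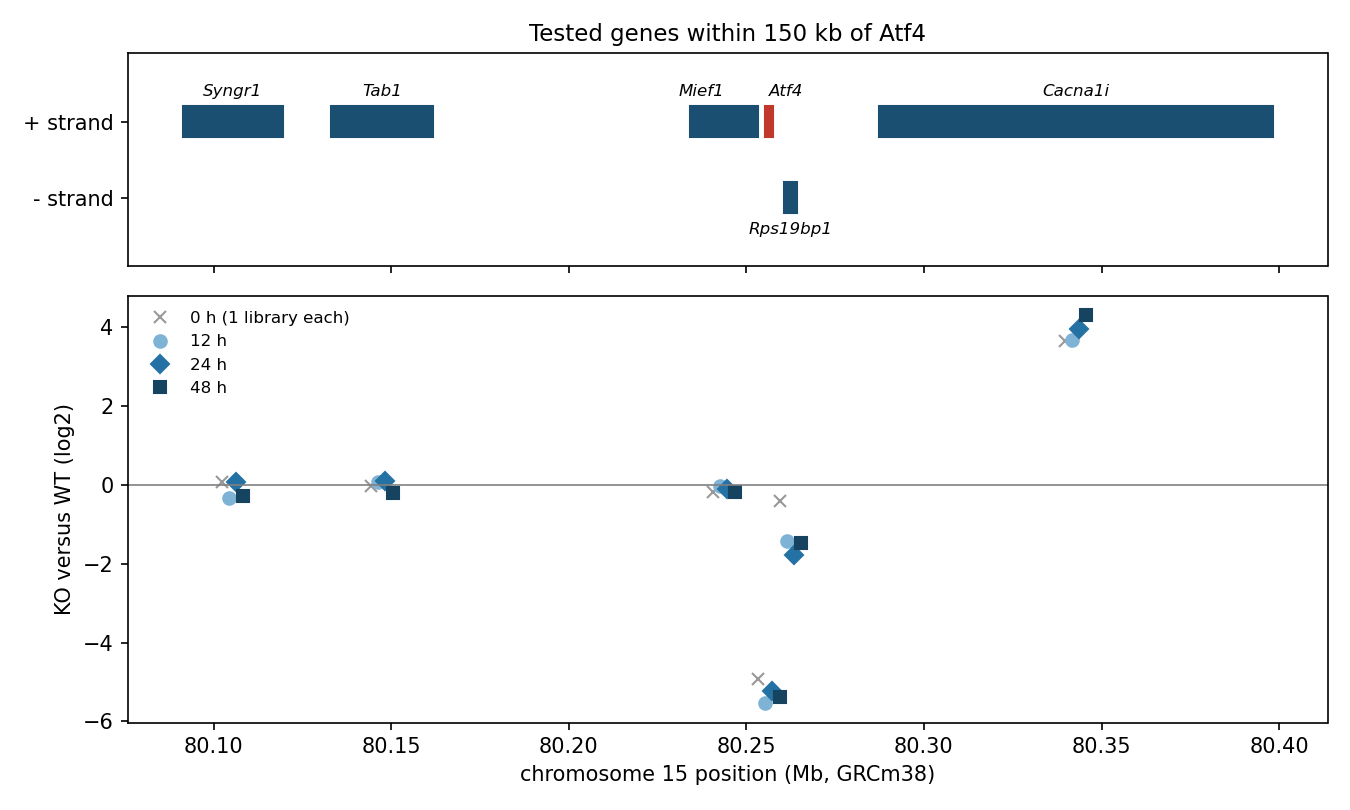
Tested genes within 150 kb of Atf4 on chromosome 15 (GRCm38, position in Mb), with their strand above and the log2 fold change of KO against WT below; each point is a gene at 1 time (0 h: 1 library per genotype). Cacna1i lies between 3.67 and 4.31 and Atf4 between -5.54 and -4.93 at all 4 times.

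At 0 h, before stimulation, the question is whether KO cells already differ. With 1 library per genotype these are differences of single values with no test. Of 7608 genes with at least 5 FPKM in 1 of the 2 libraries, 10 were at least 2-fold higher and 2 at least 2-fold lower in KO. Atf4 (log2 -4.93) and Srp54b (log2 -1.502), a signal recognition particle gene that varied widely between libraries at 12 h (13.8 ± 15.6 FPKM in KO), were the 2 lower ones. The next largest differences downward were Aars (30.1 FPKM in WT and 16.2 in KO) and Cars (11.9 and 6.14), which charge tRNA with alanine and cysteine, followed by Grhpr, Bola3, Mycbp and Zbtb45 (log2 -0.75). Cacna1i (0.319 and 15.7 FPKM), the ribosomal protein genes Rpl17 (503 and 1291) and Rpl22l1 (127 and 304), Atf3 (6.54 and 16.9) and Hspa1a (65.4 and 152) differed most in the other direction, with Sdhaf4 (log2 1.23), Atp5e (log2 1.14) and Churc1 (log2 0.97).

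The fixed lists moved little at 0 h. The percentiles below compare genes within 1 library per genotype and ignore correlation within a list. They measure no spread between libraries and are no test of genotype. The median of the cytosolic aminoacyl-tRNA synthetases was -0.16 on the log2 scale, at percentile 0.1 of random lists of like expression, and that of naive and quiescence genes was -0.12, at percentile 0.74. T cell activation markers had a median of 0.13 (percentile 99.9), cholesterol synthesis 0.10 (percentile 99.6), p53 targets 0.11 (percentile 98.9) and integrated stress response regulators 0.10 (percentile 97.3). Dendritic cell markers lay at -0.38 (percentile 0.02) and inhibitory receptors at -0.15 (percentile 2.89). The other pathway lists lay between percentile 7.2 (amino acid transporters) and 91.6 (oxidative phosphorylation), with amino acid and one-carbon synthesis enzymes at 47.7, S phase at 16.4 and glycolysis at 53.1.

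At 12 h KO against WT asks which genes differ early in activation. Genes of tRNA charging and amino acid synthesis fell. Cars fell from 38.4 ± 3.03 to 7.42 ± 0.894 FPKM, 4.68-fold lower (adjusted p = 0.000229), and Aars from 68.2 ± 4.83 to 21.5 ± 0.762 (adjusted p = 0.000229). Asns, which makes asparagine, fell from 5.97 ± 2.42 to 0.739 ± 0.0087 FPKM (adjusted p = 0.0129), and Phgdh, the first enzyme of serine synthesis, from 130.4 ± 4.18 to 64.3 ± 4.92 (adjusted p = 0.00509). Cdc6, which loads the replicative helicase, fell from 2.87 ± 0.605 to 0.642 ± 0.162 FPKM (adjusted p = 0.00747). In all, 43 of 10746 genes changed, of which 2 rose and 41 fell, and 999 had an unadjusted p under 0.05. The 2 that rose were Cacna1i and Psd, an exchange factor for a small GTPase (1.52-fold, adjusted p = 0.0471).

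Of 16 amino acid and one-carbon synthesis enzymes tested at 12 h, 7 fell and none rose (13 fell when adjusted over the list alone), with a median log2 fold change of -0.74 (camera adjusted p = 3.18e-22, and adjusted p = 0.065 with an estimated correlation). Pycr1, which makes proline, fell by 1.52 on the log2 scale and Gpt2 by 0.90. Of 20 cytosolic aminoacyl-tRNA synthetases, 7 fell (10 fell and 1 rose when adjusted over the list alone; camera adjusted p = 4.06e-13, and adjusted p = 0.065 with an estimated correlation), with Yars at -1.29 and Iars at -1.03. Of 11 amino acid transporters, 2 fell, Slc1a4 (log2 -2.00) and Slc6a9 (log2 -1.49), and 6 fell when adjusted over the list alone (camera adjusted p = 1.77e-06, and adjusted p = 0.065 with an estimated correlation). Of 13 integrated stress response regulators, Trib3 (log2 -1.46) and Eif4ebp1 (log2 -0.97) fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00116, and adjusted p = 0.132 with an estimated correlation). None of 17 ER chaperone and folding genes passed over all genes and 7 fell when adjusted over the list alone, with a median of -0.19 (camera adjusted p = 4.63e-08, and adjusted p = 0.0833 with an estimated correlation).

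S phase genes and some mitosis genes were lower at 12 h. Of 26 S phase and DNA replication genes, 7 fell and 19 fell when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.49e-21, and adjusted p = 0.0281 with an estimated correlation). Uhrf1, which maintains DNA methylation at replication, fell from 28.0 to 15.6 FPKM (adjusted p = 0.00404), and Cdc45 (log2 -0.76) and E2f1 (log2 -0.69) fell too. Of 20 G2 and mitosis genes, 2 fell, Top2a (log2 -0.81) and Bub1b (log2 -0.65), and 6 when adjusted over the list alone (camera adjusted p = 1.74e-09, and adjusted p = 0.065 with an estimated correlation). The list of 12 G1 cyclins, kinases and inhibitors had no gene past the threshold and did not pass (camera adjusted p = 0.176).

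Cholesterol synthesis genes had a median of -0.41 at 12 h, with none of 20 past the threshold over all genes and 19 lower when adjusted over the list alone (camera adjusted p = 2.23e-19, and adjusted p = 0.137 with an estimated correlation). Ribosome biogenesis genes had a median of 0.14, with 0 of 22 past the threshold over all genes in limma and 1 higher when adjusted over the list alone (camera adjusted p = 3.82e-09, and adjusted p = 0.293 with an estimated correlation). T cell activation markers had a median of 0.08 (camera adjusted p = 0.0122, and adjusted p = 0.495 with an estimated correlation), which did not hold without KO library 3 (adjusted p = 0.561). Glycolysis genes had a median of -0.09 (camera adjusted p = 0.0219, and adjusted p = 0.341 with an estimated correlation), which did not hold without WT library 2 (adjusted p = 0.177) or KO library 2 (adjusted p = 0.231). Naive and quiescence genes, inhibitory receptors, p53 targets and the BCL2 family (camera adjusted p = 0.845 for each), glutathione genes (0.705), interferon-stimulated genes and oxidative phosphorylation (0.872 for both) did not pass. Cytotoxic effector genes (adjusted p = 0.394) passed only without KO library 2 (0.00639). Camera gave this list, inhibitory receptors and oxidative phosphorylation a positive direction although their medians were -0.07, -0.01 and -0.01.

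The number of genes changed at 12 h rested on all 4 libraries: it was 8 without WT library 2, 13 without WT library 3, 9 without KO library 2 and 10 without KO library 3. Without the filter on low values it was 19, and Asns, Phgdh, Yars, Cdc6, Rps19bp1, Gpt2, Trib3, Eif4ebp1, E2f1, Bub1b and Psd did not pass. With only the 4 libraries of 12 h in the fit it was 197, of which 136 fell. Psd also missed with a pseudocount of 5 (adjusted p = 0.0664) and with Atf4 and its neighbours left out (0.0506). The calls of Atf4, Cacna1i, Cars, Aars, Pycr1, Slc1a4 and Slc6a9 held without each of the 4 libraries, and those of the other named genes at 12 h did not hold without at least 1 of them.

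**Figure D2:**
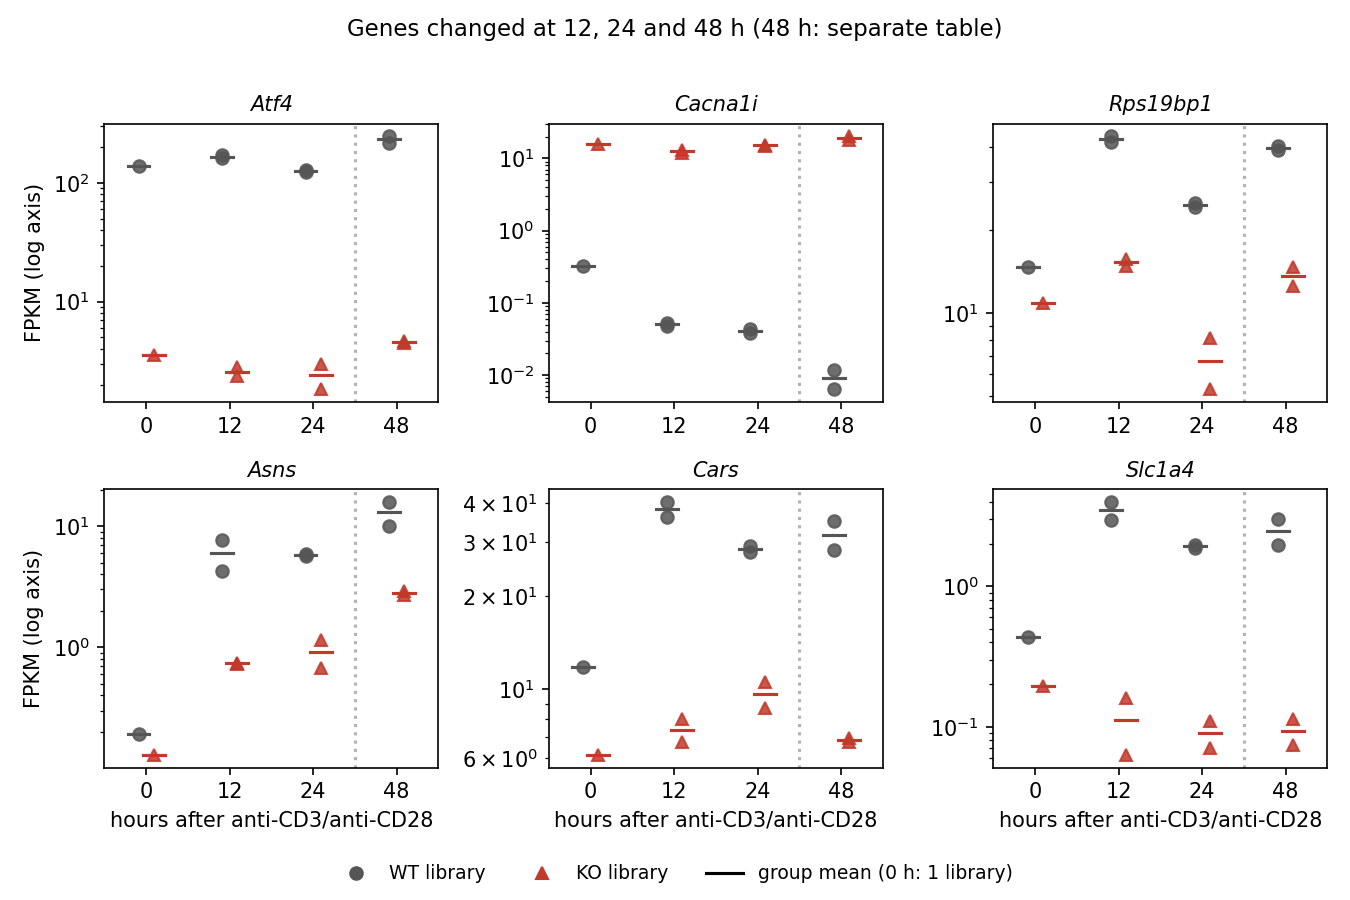
FPKM on a log axis against hours after stimulation for 6 genes changed at 12, 24 and 48 h, with 1 point per library and a line at the group mean; the dotted line parts the separate 48 h table. At 12 h Cars is at 38.4 FPKM in WT and 7.42 in KO, and Cacna1i at 0.0507 and 12.5.

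At 24 h the same comparison asks how far the KO cells have progressed toward division. Mitosis genes fell in KO and genes of the resting T cell rose. Ube2c, which starts the degradation of mitotic regulators, fell from 99.3 ± 38.9 to 18.4 ± 0.664 FPKM (4.98-fold lower, adjusted p = 0.000493), and Mki67, the proliferation antigen, from 141 ± 36.4 to 30.1 ± 0.0289 (4.49-fold lower, adjusted p = 0.000211). Klf2, a transcription factor of resting T cells, rose from 32.0 ± 0.482 to 111 ± 4.41 FPKM (3.4-fold, adjusted p = 1.6e-05), and its target S1pr1, the receptor for exit from lymph nodes, from 21.4 ± 0.742 to 59.6 ± 7.25 (2.7-fold, adjusted p = 0.00019). Of 10746 genes, 3891 changed, of which 2315 (59.5%) rose and 1576 fell. Scaling by size factors turned that split to 1657 that rose (42.8%) and 2216 that fell. Changes of at least 2-fold were 85 rises and 140 falls. After Cacna1i and Klf2, the largest rises were those of Rhob, S1pr4 (15.9 ± 4.63 to 52.3 ± 1.08 FPKM), Hist1h1e, Slc6a19, Prss12 (log2 1.44) and S1pr1. After Atf4, Ube2c and Mki67, the largest falls were those of Plk1, Hmmr, Ckap2l, Nusap1 and Tpx2 (log2 -1.90).

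All 20 G2 and mitosis genes fell at 24 h, with a median of -1.71 (20 when adjusted over the list alone; camera adjusted p = 3.51e-20, and adjusted p = 0.0281 with an estimated correlation). Of 26 S phase genes, 22 fell and none rose (24 adjusted over the list alone; camera adjusted p = 6.45e-14, and adjusted p = 0.0376 with an estimated correlation). They include the ribonucleotide reductase genes Rrm2 (152 to 67.2 FPKM) and Rrm1 (log2 -1.09) and the thymidylate synthase Tyms (log2 -1.10). Of 12 G1 genes, 7 fell and 1 rose over all genes and over the list alone, with E2f3 at -0.88 and Ccnd2 at -0.52 (camera adjusted p = 0.0151, and adjusted p = 0.187 with an estimated correlation). Without WT library 2 the adjusted p of this list was 0.0668.

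Amino acid genes remained lower at 24 h. Cars (log2 -1.47), Iars (log2 -1.09), Aars (log2 -1.03) and Yars (log2 -0.97) fell, as did 14 of 20 synthetases in all, and 1 rose (15 and 2 adjusted over the list alone; camera adjusted p = 8.47e-07, and adjusted p = 0.137 with an estimated correlation). Of 16 synthesis enzymes, 10 fell (11 adjusted over the list alone), including Asns (log2 -1.84), Pycr1 (log2 -0.90) and the mitochondrial folate enzymes Mthfd2 (log2 -0.83) and Shmt2 (log2 -0.69) (camera adjusted p = 1.16e-06, and adjusted p = 0.187 with an estimated correlation). Of 11 transporters, 5 fell over all genes and over the list alone, with Slc1a4 at -1.42 and the large neutral amino acid transporter Slc7a5 at -0.61 (camera adjusted p = 0.00362, and adjusted p = 0.167 with an estimated correlation). Of 17 ER chaperone and folding genes, 5 fell and 1 rose over all genes and over the list alone, with Hsp90b1 at -0.42 and Edem1 at 0.40 (camera adjusted p = 0.0156, and adjusted p = 0.293 with an estimated correlation). With size factors 8 of them fell. The 13 integrated stress response regulators had 2 rises, among them Ddit4 (log2 0.74), and 2 falls (2 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.623).

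T cell activation markers fell at 24 h, 13 of 20 over all genes and over the list alone, with a median of -0.52 (camera adjusted p = 1.27e-08, and adjusted p = 0.242 with an estimated correlation). Nr4a3, induced by T cell receptor signals, fell from 63.8 ± 2.84 to 25.8 ± 4.14 FPKM (adjusted p = 0.000344). Il2ra, a chain of the IL-2 receptor, fell from 89.3 ± 17.4 to 47.4 ± 3.64 (adjusted p = 0.00257), and the transferrin receptor Tfrc fell by 0.90 on the log2 scale. Of 19 cytotoxic effector genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00442, and adjusted p = 0.462 with an estimated correlation). Without KO library 2 the adjusted p of this list was 0.0552. Its largest falls, the chemokine Ccl3 (log2 -1.55), the cytokine Ifng (log2 -1.46) and the transcription factor Tbx21 (log2 -1.30), did not hold without KO library 2 (adjusted p = 0.108, 0.0544 and 0.186), and Tbx21 did not hold without WT library 2 (adjusted p = 0.0686). Of 8 inhibitory receptors, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with Cd160 at -0.95 and Btla at -0.65 (camera adjusted p = 0.00726, and adjusted p = 0.178 with an estimated correlation). Of 17 naive and quiescence genes, 12 rose and none fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000113, and adjusted p = 0.283 with an estimated correlation). Il7r, the IL-7 receptor, rose from 40.4 ± 5.31 to 81.2 ± 10.4 FPKM (adjusted p = 0.00112).

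Of 18 interferon-stimulated genes, 11 rose and 1 fell at 24 h over all genes and over the list alone (camera adjusted p = 0.00158, and adjusted p = 0.132 with an estimated correlation). Irf7 rose from 7.54 ± 1.04 to 18.3 ± 0.0534 FPKM (adjusted p = 0.000233) and Ifit3 by 1.02 on the log2 scale. Of 12 p53 targets, 7 rose and 1 fell over all genes and over the list alone, among them the pro-death gene Bbc3 (8.27 to 20.02 FPKM), Phlda3 (log2 1.05) and Bax (log2 0.81) (camera adjusted p = 0.0151, and adjusted p = 0.187 with an estimated correlation). Without WT library 3 the adjusted p of this list was 0.1. Of 22 ribosome biogenesis genes, 9 fell (12 adjusted over the list alone), with nucleolin, Ncl, at -0.66 (camera adjusted p = 6.7e-06, and adjusted p = 0.35 with an estimated correlation). With size factors 16 of them fell. Of 18 glycolysis genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone), with Hk2 at -0.57 and Tpi1 at -0.47 (camera adjusted p = 0.00456, and adjusted p = 0.293 with an estimated correlation). The lists of cholesterol synthesis (3 rises and 3 falls, adjusted p = 0.0938), glutathione defence (3 falls, with Hmox1 at -0.72, adjusted p = 0.0938), the BCL2 family (4 rises, adjusted p = 0.394) and oxidative phosphorylation (3 rises and 1 fall of 25, adjusted p = 0.471) did not pass. These counts were equal when adjusted over the list alone except for oxidative phosphorylation (0 and 1). Without a filter the glutathione list passed (adjusted p = 0.0189). Oxidative phosphorylation passed only without WT library 3 (adjusted p = 0.000359).

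The number of genes changed at 24 h was 1672 without KO library 2, 2167 without KO library 3 and 2021 with only the 4 libraries of 24 h in the fit. The call of Hist1h1e did not hold without KO library 2 (adjusted p = 0.0727) or KO library 3 (adjusted p = 0.0667).

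**Figure D3:**
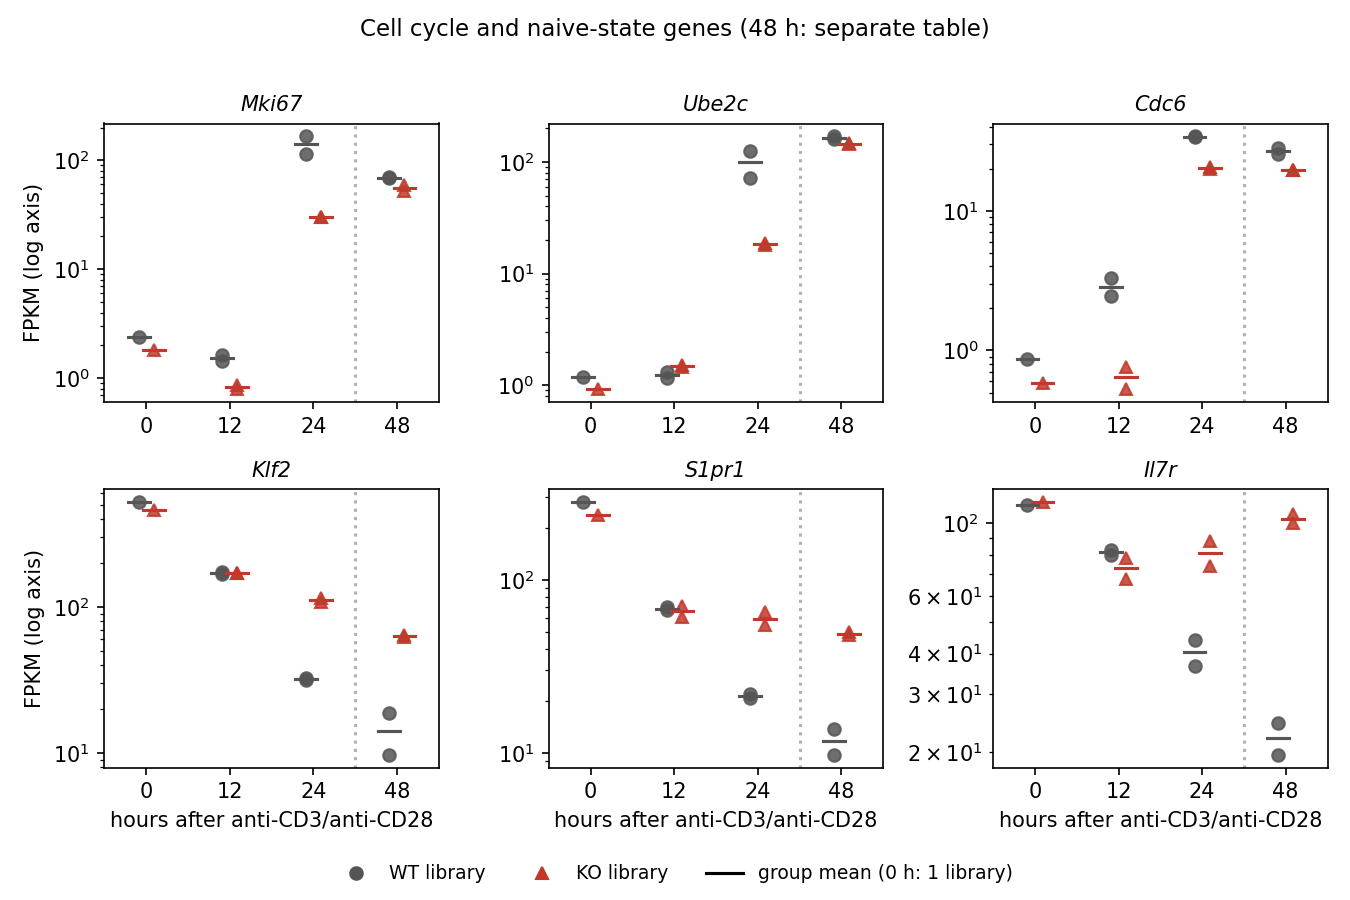
FPKM on a log axis against hours after stimulation for 3 cell cycle genes and 3 naive-state genes, with 1 point per library and a line at the group mean; the dotted line parts the separate 48 h table. At 24 h Mki67 is at 141 FPKM in WT and 30.1 in KO, and Klf2 at 32.0 and 111.

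At 48 h KO against WT asks what differs later in activation. The tRNA synthetase genes Cars1 (31.7 ± 4.90 to 6.85 ± 0.159 FPKM, 4.14-fold lower, adjusted p = 0.00108), Yars1 (62.0 ± 9.58 to 16.5 ± 0.145, adjusted p = 0.00108) and Aars1 (48.9 ± 6.37 to 15.1 ± 0.424, adjusted p = 0.00108) fell. Asns fell from 12.96 ± 4.10 to 2.80 ± 0.139 FPKM (adjusted p = 0.00148). The glycolytic enzyme gene Tpi1 fell from 414 ± 75.8 to 129 ± 15.6 FPKM (adjusted p = 0.00123) and the lactate exporter Slc16a3 by 1.82 on the log2 scale (adjusted p = 0.00422). Il7r rose from 22.1 ± 3.49 to 103 ± 4.35 FPKM (4.55-fold, adjusted p = 0.00108). Of 11902 genes, 5845 changed, of which 3210 (54.9%) rose and 2635 fell. The larger share fell with size factors (2807 rose and 3054 fell), after quantile normalisation (2394 and 2591) and with a filter of 5 FPKM (2289 and 2626). Rises of at least 2-fold numbered 472 and falls 129. The share of FPKM in protein-coding genes was 95.2% and 96% in WT libraries 1 and 2 and 91.6% and 92.3% in KO libraries 1 and 2, the 10 highest genes held at most 7.3% in WT and at most 10.5% in KO, and 19547 to 20002 genes were above 0 in WT and 22251 to 24043 in KO. With protein-coding genes alone, rescaled to the same total in each library, 6157 changed and 4607 of them rose (74.8%), and the median of all genes moved from 0.06 to 0.20.

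After Cacna1i, the largest rises at 48 h were in noncoding transcripts, receptor segments and Lars2. Malat1, a nuclear noncoding RNA, rose from 82.6 ± 33.6 to 527 ± 34.4 FPKM (6.58-fold, adjusted p = 0.0013). The row of Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, rose from 208 ± 92.2 to 1115 ± 28.6 (adjusted p = 0.00159). Whether all reads counted for Lars2 came from its own transcript was not tested, so its value is uncertain. The microRNA genes Mir5123 and Mir7227 and the T cell receptor α joining segments Traj18, Traj35 and Traj15 rose too, with Mir5123 and Traj35 listed at 0 in WT. Mir5123 and Mir7227 lie in introns of B4galt1 and Arid1a. Gapdh fell by 2.70 on the log2 scale, and its values are uncertain because many pseudogenes share its sequence and its libraries ranged widely at 12 h (50.6 ± 49.7 FPKM in WT).

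Most genes of amino acid synthesis and tRNA charging fell at 48 h, and no list of this paragraph passed with an estimated correlation. Of 15 synthesis enzymes, 14 fell over all genes and over the list alone, including Phgdh (263 ± 34.5 to 107 ± 8.95 FPKM, adjusted p = 0.00123), Shmt2 (log2 -1.10) and Mthfd2 (log2 -1.06) (camera adjusted p = 9.66e-08, and adjusted p = 0.341 with an estimated correlation). Of 20 tRNA synthetases, 18 fell over all genes and over the list alone, with a median of -0.77 (camera adjusted p = 6.26e-10, and adjusted p = 0.35 with an estimated correlation). Of 9 transporters, 4 fell over all genes and over the list alone, with Slc1a4 at -1.65 and Slc7a5 at -0.77 (camera adjusted p = 0.0115, and adjusted p = 0.461 with an estimated correlation). With a filter of 5 FPKM the adjusted p of the transporters was 0.0668, and after quantile normalisation 0.169. Of 13 integrated stress response regulators, 7 fell over all genes and over the list alone, with Eif4ebp1 at -1.12 and Chac1 at -1.05 (camera adjusted p = 0.00116, and adjusted p = 0.211 with an estimated correlation). Of 17 ER chaperone and folding genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone), with Creld2 at -0.99 and Manf at -0.92 (camera adjusted p = 5.23e-05, and adjusted p = 0.283 with an estimated correlation).

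Most members of the lists of glycolysis, oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis and glutathione defence fell at 48 h. The 13 mitochondrially encoded genes, a family outside these lists, went the other way, with 11 rises and 0 falls. Of 18 glycolysis genes, 17 fell over all genes and over the list alone, with a median of -0.90 and Eno1 falling from 998 ± 174.7 to 382 ± 9.69 FPKM (camera adjusted p = 1.27e-08, and adjusted p = 0.346 with an estimated correlation). Of 25 oxidative phosphorylation genes, 22 fell (23 adjusted over the list alone), with cytochrome c, Cycs, at -0.91 and the ATP synthase gene Atp5f1b at -0.88 (camera adjusted p = 9.87e-10, and adjusted p = 0.341 with an estimated correlation). Of 22 ribosome biogenesis genes, 19 fell over all genes and over the list alone, with Nolc1 at -0.96 (camera adjusted p = 8.97e-09, and adjusted p = 0.335 with an estimated correlation). After quantile normalisation 14 oxidative phosphorylation genes fell, with a median of -0.23 in place of -0.55, and 11 ribosome biogenesis genes, with a median of -0.22 in place of -0.49. Of 20 cholesterol synthesis genes, 13 fell (17 adjusted over the list alone), with Fdps at -1.34 and Lss at -0.89 (camera adjusted p = 1.56e-05, and adjusted p = 0.506 with an estimated correlation). Of 14 glutathione and oxidative stress genes, 8 fell over all genes and over the list alone, with superoxide dismutase, Sod1, at -0.90 (camera adjusted p = 0.00299, and adjusted p = 0.318 with an estimated correlation).

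Cell cycle genes were lower in KO at 48 h as well. Of 26 S phase genes, 23 fell (24 adjusted over the list alone), with a median of -0.41, and of 20 G2 and mitosis genes 14 fell over all genes and over the list alone, with a median of -0.38 and Plk1 at -0.83. The S phase list passed (camera adjusted p = 4.24e-09, and adjusted p = 0.335 with an estimated correlation), as did the mitosis list (camera adjusted p = 1.53e-06, and adjusted p = 0.354 with an estimated correlation). After quantile normalisation 16 S phase genes fell, with a median of -0.27, and 9 mitosis genes, with a median of -0.21, and after the protein-coding rescaling the medians were -0.22 and -0.18. Of 12 G1 genes, 7 fell, with Cdk4 at -0.63, and 2 rose, the cell cycle inhibitor genes Cdkn1b (log2 0.81) and Rb1 (log2 0.48), over all genes and over the list alone. Its camera adjusted p = 0.0487 (adjusted p = 0.333 with an estimated correlation) was 0.0679 without WT library 2, 0.0733 without KO library 2, 0.0521 without KO library 1 and 0.244 after quantile normalisation.

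T cell genes moved in both directions at 48 h. Of 17 naive and quiescence genes, 15 rose (16 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 7.15e-07, and adjusted p = 0.382 with an estimated correlation). Klf2 rose from 14.2 ± 6.42 to 63.4 ± 1.65 FPKM (adjusted p = 0.00195) and S1pr1 from 11.7 ± 2.83 to 48.9 ± 1.31 (adjusted p = 0.00108). Of 21 T cell activation markers, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with the AP-1 factors Batf3 at -1.64 and Batf at -1.17 (camera adjusted p = 0.00143, and adjusted p = 0.211 with an estimated correlation). After quantile normalisation the adjusted p of the activation markers was 0.244. Of 17 cytotoxic effector genes, 11 fell and 2 rose (11 and 4 adjusted over the list alone), with Tbx21 falling from 18.4 ± 2.34 to 6.23 ± 0.36 FPKM (camera adjusted p = 0.00362, and adjusted p = 0.475 with an estimated correlation). Of 8 inhibitory receptors, 5 fell and 1 rose over all genes and over the list alone, with Pdcd1 at -0.64 and Cd274 at 0.74, and the list did not pass (camera adjusted p = 0.0552). It passed without WT library 2 (0.0196), without KO library 1 (0.0492) and without a filter (0.0016). Of 17 interferon-stimulated genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone), with Irf7 at 0.88, and the list did not pass (adjusted p = 0.0602). It passed without WT library 1 (0.0421), with a filter of 5 FPKM (0.0325) and with size factors (0.0454). After quantile normalisation 6 interferon-stimulated genes rose and 3 fell, with a median of 0.19. The 12 p53 targets (2 rises, 3 falls, adjusted p = 0.705) and the 13 BCL2 family genes (2 rises, 6 falls, adjusted p = 0.23) did not pass, with the same counts adjusted over the list alone. The median of the BCL2 family was -0.17, and 0.03 after the protein-coding rescaling, and the list passed without a filter (adjusted p = 0.0232).

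No gene passed at 48 h in limma without KO library 1, where 4667 genes had an unadjusted p under 0.05, and the number was 2094 without KO library 2. Of the genes named at 48 h, Klf2, Slc16a3, Slc7a5, Fdps, Lss, Eif4ebp1, Cdkn1b and Rb1 also missed the threshold without KO library 2. The 2 residual degrees of freedom of the 48 h fit become 1 when a library is left out.

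**Figure D4:**
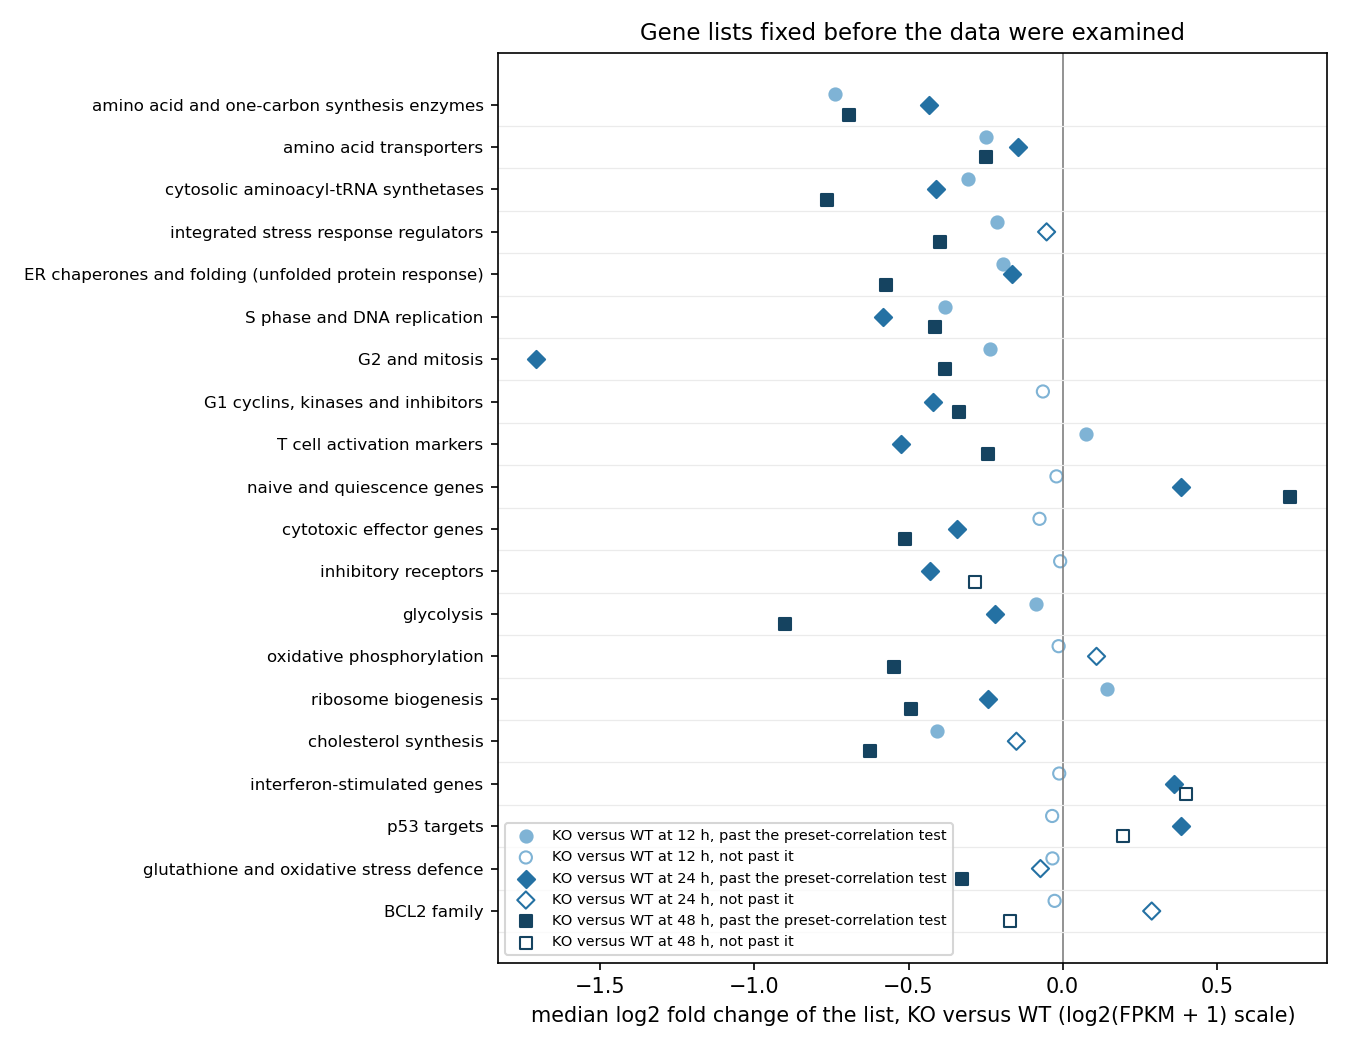
Median log2 fold change of KO against WT for each of the 20 pathway lists (x axis, log2 scale) at 12, 24 and 48 h, with filled symbols where camera with a preset correlation passed an adjusted p of 0.05. The G2 and mitosis list is lowest at 24 h (-1.71) and the naive and quiescence list highest at 48 h (0.74), and the 48 h median of the BCL2 family flips to 0.03 with protein-coding rescaling.

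Across times, 31 genes fell at 12, 24 and 48 h where 1.47 would be shared by chance, and 1 gene rose at all 3 times, Cacna1i. The chance figures here assume independent calls. Calls at 12 and 24 h share 1 fit and 1 spread per gene, so these figures are only a rough guide. The largest mean falls were those of Atf4 (log2 -5.38), Cars (log2 -1.92), Asns (log2 -1.88), Slc1a4 (log2 -1.69) and Rps19bp1 (log2 -1.56). Over 9932 genes tested in both tables, 961 rose at both 24 and 48 h (523 by chance) and 702 fell at both (385 by chance), while 377 went in opposite directions (916 by chance). In all, 1671 genes were called in the same direction at 2 or more times, of which 962 (57.6%) rose. That split was 673 of 1692 (39.8%) with size factors, and without a filter 1006 genes were called. Bax and Pfkm rose at 24 h and fell at 48 h, and Rb1 fell at 24 h and rose at 48 h.

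More genes changed from 0 to 12 h than from 12 to 24 h in both genotypes, and 24 to 48 h was not compared. In WT 7387 genes changed, of which 4505 rose (61%) and 2882 fell, and in KO 7369, of which 4535 rose (61.5%) and 2834 fell. With size factors 48.7% rose in WT and 48.3% in KO, as the median of all genes moved from 0.18 to -0.02 in WT and from 0.19 to -0.03 in KO. The chemokine gene Xcl1 rose most (log2 7.86 in WT and 8.47 in KO), then Tnfrsf9, a costimulatory receptor (log2 5.84 and 6.28), Il2ra (log2 5.66 and 5.99) and the chemokine Ccl4 (log2 5.39 and 5.60), followed by Lag3 in WT and Pdcd1 in KO. The heat shock genes Hspa1b (log2 -6.83 in WT and -7.71 in KO) and Hspa1a (log2 -5.998 and -7.20) fell most, then Fosb, Klf4 and, in WT, Vps37b or, in KO, Tnfaip3.

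All 20 tRNA synthetases rose from 0 to 12 h in WT, with a median of 1.47 (camera adjusted p = 4.58e-07, and adjusted p = 0.328 with an estimated correlation). In KO 19 of them rose, with a median of 1.19 (camera adjusted p = 1.5e-05, and adjusted p = 0.339 with an estimated correlation). Of the amino acid synthesis enzymes, 13 rose and 1 fell in WT, with a median of 1.78 (camera adjusted p = 0.00316, and adjusted p = 0.472 with an estimated correlation). In KO 9 of the enzymes rose and 2 fell, with a median of 0.98 (camera adjusted p = 0.155, and 0.0418 without a filter). All 22 ribosome biogenesis genes rose in both WT (camera adjusted p = 2.65e-06, and adjusted p = 0.539 with an estimated correlation) and KO (camera adjusted p = 6.57e-07, and adjusted p = 0.533 with an estimated correlation). S phase genes rose, 21 in WT (camera adjusted p = 0.000192, and adjusted p = 0.318 with an estimated correlation) and 18 in KO (camera adjusted p = 0.0116, and adjusted p = 0.342 with an estimated correlation). Naive and quiescence genes fell, 13 in WT (camera adjusted p = 0.000471, and adjusted p = 0.451 with an estimated correlation) and 13 in KO (camera adjusted p = 0.000626, and adjusted p = 0.451 with an estimated correlation).

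From 12 to 24 h, 4562 genes changed in WT, of which 2075 rose and 2487 fell, and 3847 in KO, of which 2414 rose (62.8%) and 1433 fell. With size factors 48.7% of the changed genes rose in KO. Mki67 rose 55.4-fold in WT (adjusted p = 2.34e-07) and 17-fold in KO (adjusted p = 2.56e-06), and Rrm2 by 4.86 and 4.09 on the log2 scale. The other largest rises were Ube2c, Nusap1 and Ccna2 in WT and Cdc6, Spc24 and Hist1h3c in KO. In WT the largest falls were Klf2 (log2 -2.38), Rhob, Tsc22d3, S1pr4 and S1pr1 (log2 -1.62). In KO they were Lilr4b and Lilrb4a, which are uncertain because the 2 genes are nearly identical, Ramp3, Xcl1 (log2 -1.36) and Srgn. All 20 mitosis genes rose in both genotypes, with a median of 4.02 in WT (camera adjusted p = 4.37e-22, and adjusted p = 0.0297 with an estimated correlation) and 2.84 in KO (camera adjusted p = 4.1e-18, and adjusted p = 0.0297 with an estimated correlation). All 26 S phase genes rose in both, with a median of 1.68 in WT and 1.53 in KO. T cell activation markers went apart, with 10 rises and 2 falls in WT and 3 rises and 8 falls in KO (camera adjusted p = 0.00778, and adjusted p = 0.633 with an estimated correlation). The KO call was lost after quantile normalisation (adjusted p = 0.086), and that of WT (adjusted p = 0.0177, and adjusted p = 0.655 with an estimated correlation) without WT 24 h library 2 (0.07). Of 22 ribosome biogenesis genes, 20 fell in KO (camera adjusted p = 3.43e-13, and adjusted p = 0.424 with an estimated correlation) and 9 in WT (camera adjusted p = 0.0406, and adjusted p = 0.743 with an estimated correlation). The WT call was lost with size factors (adjusted p = 0.0659), after quantile normalisation (0.107), with a filter of 5 FPKM (0.08), without WT 12 h library 2 (0.121) and without WT 24 h library 3 (0.207). Without WT 12 h library 2 or 3 the WT count was 2796 or 2833. Without KO 12 h library 2 or 3 the KO count was 2218 or 1969, and without KO 24 h library 2 or 3 it was 1870 or 2236.

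The difference between genotypes itself changed from 12 to 24 h in 1882 genes, of which 1189 (63.2%) rose and 693 fell. With size factors 799 (42.7%) rose and 1074 fell. Klf2 (log2 1.76, adjusted p = 0.000676), S1pr4 (log2 1.68), Ypel3, S1pr1 and Tcp11l2 (log2 1.48) shifted most toward KO, and the mitosis genes Ube2c (log2 -2.47, adjusted p = 0.00561), Hmmr, Plk1 and Cenpf (log2 -1.88) shifted most away from it. The chemokine gene Ccl3 (log2 -1.86, adjusted p = 0.0472) passed without WT 24 h library 2 or 3 and missed without each of the other 6 libraries, with adjusted p up to 0.164, and Plk1 missed without KO 24 h library 2 (adjusted p = 0.0501). Among lists, 19 of 20 mitosis genes fell in this sense (camera adjusted p = 7.23e-20, and adjusted p = 0.0297 with an estimated correlation). There were falls in 11 of 20 T cell activation markers (camera adjusted p = 2.87e-09, and adjusted p = 0.414 with an estimated correlation) and rises in 9 of 17 naive genes (camera adjusted p = 0.00033, and adjusted p = 0.451 with an estimated correlation). The number of genes was 1188 without a filter. It was 610 without WT 12 h library 2, 291 without WT 12 h library 3, 3068 without WT 24 h library 2, and 4055 without WT 24 h library 3. It was 644 without KO 12 h library 2, 320 without KO 12 h library 3, 291 without KO 24 h library 2 and 590 without KO 24 h library 3.

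Marker genes show the cells in the libraries. Cd8a lay between 205 and 296 FPKM at 0 to 24 h. Of 8 CD8 T cell genes, 3 rose at 24 h (camera adjusted p = 0.721), where 1 rose and 1 fell with size factors, and 1 rose and 2 fell at 48 h (median -0.12, camera adjusted p = 0.785), where the median was 0.17 after quantile normalisation and 0.08 after protein-coding rescaling. None of the marker lists had a gene past the threshold at 12 h in limma. The CD8 T cell genes had a median of -0.095 there (camera adjusted p = 0.124), with Cd8a at 287 FPKM in WT and 242 in KO and Cd8b1 at 281 and 226, and the list passed downward after quantile normalisation (adjusted p = 0.0185) and with the 4 libraries of 12 h alone (0.0195). The change of its difference from 12 to 24 h (camera adjusted p = 0.062) passed without a filter (0.0195), after quantile normalisation (0.0362) and without WT 24 h library 2 (0.00779). At 24 h none of 6 B cell, 4 dendritic cell, 3 CD4 T cell, 3 erythrocyte, 4 sex-linked and 1 myeloid genes tested passed, and no NK cell or γδ T cell gene was expressed highly enough to test. The 1 stroma and endothelium gene tested, Pecam1, which CD8 T cells also express, rose from 31.4 ± 1.33 to 37.3 ± 2.14 FPKM at 24 h (adjusted p = 0.0287) and by 0.56 on the log2 scale at 48 h (adjusted p = 0.00521). With size factors its log2 change at 24 h was 0.15 and did not pass. At 48 h the γδ receptor gene Trdc rose by 1.52 (adjusted p = 0.00108), the dendritic and B cell gene Cd74 fell by 0.64 (adjusted p = 0.00182). Further, 1 of 3 B cell genes rose, 1 of 2 myeloid genes rose and the other fell, and 3 of 4 sex-linked genes rose. The highest value of a B cell marker at 48 h was 207.5 FPKM (Ighm), and that of a CD8 T cell gene 293.6 (Lat). After quantile normalisation 2 B cell genes rose, 2 dendritic cell genes fell and no myeloid gene rose. The CD4 T cell gene tested did not change at 48 h, and no erythrocyte gene was tested there. At 0 h Cd74 was 86.1 FPKM in WT and 56.7 in KO. The Y-linked gene Ddx3y lay between 24.7 and 120.2 FPKM in all libraries.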

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

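The tests of slower progress, of depth and of the amino acid genes were chosen only after the result was seen, and that of scaling before it.

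The difference between KO and WT changed from 12 to 24 h in 1882 genes, by a test of the change itself in limma. Klf2 (log2 1.76), S1pr4 (1.68), Ypel3 (1.49), S1pr1 (1.48) and Tcp11l2 (1.48) moved most toward KO, and Ube2c (-2.47), Hmmr (-1.97), Plk1 (-1.95), Cenpf (-1.88) and Ccl3 (-1.86) most away from it. Among lists, the median change was -1.52 for G2 and mitosis, -0.11 for S phase and DNA replication, -0.62 for T cell activation markers, 0.49 for naive and quiescence genes, -0.58 for cytotoxic effector genes, -0.50 for inhibitory receptors, -0.41 for ribosome biogenesis, 0.33 for cholesterol synthesis, 0.39 for interferon-stimulated genes and 0.48 for p53 targets. With an estimated correlation only the G2 and mitosis list passed (adjusted p = 0.0297). The cytotoxic list did not pass without KO 12 h library 3 (adjusted p = 0.0728) or KO 24 h library 2 (0.0582), the cholesterol list without KO 12 h library 3 (0.104) and the p53 targets without WT 24 h library 3 (0.131). The gene count without 1 library ran from 291 (without WT 12 h library 3, or without KO 24 h library 2) to 4055 (without WT 24 h library 3).

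At 24 h the KO libraries lay between the WT libraries of 12 and 24 h. Placed on the course from 0 at 12 h to 1 at 24 h of the WT libraries with the other number, the KO 24 h libraries lay at 0.529 and 0.467, the WT 24 h libraries at 0.942 and 0.795 and the KO 12 h libraries at -0.088 and -0.062. Lower depth of the KO libraries is argued against by a depth ratio of 0.939, and scaling as the whole cause by the 1873 genes with a changed difference after median-of-ratios scaling, of which 1492 were among the 1882, although the share that rose moved from 63.2% to 42.7%. Slower progress along the WT course may account for part of the pattern. Across genes, which are not independent replicates, the WT change was correlated with the KO difference against the other WT library. The r was -0.548 for one split of the libraries and -0.558 for the other. WT 24 h libraries entered both sides with opposite sign, so a shift shared by both of them would also give a negative r. Separate effects of ATF4 loss on single genes stay open, as do differences between cultures, since the labels do not say whether the genotypes were cultured side by side.

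The amino acid synthesis, transporter and tRNA synthetase genes were lower in KO at 24 h beyond that course. Once the fitted share of the WT course was taken off each gene, the median of the 47 genes of the 3 lists was -0.405, and 42 of them were negative. Slower progress alone would have left them near 0. The S phase (0.05) and G1 (0.003) lists were left near 0. The share was fitted over all genes, with most weight on those that changed most in WT. Small residues of cell cycle genes are therefore no check of the course. The residue was not particular to amino acid genes: the median left was -0.43 for T cell activation markers, -0.38 for inhibitory receptors, -0.37 for cytotoxic effector genes, -0.33 for ribosome biogenesis and -0.25 for G2 and mitosis. A direct requirement for ATF4 is a candidate explanation that stays untested here, as does a broader difference in activation.

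Genes called in opposite directions at 24 and 48 h numbered 377, and the difference between these times was not tested because the tables differ in gene set and scale. They include Bax (log2 0.81 at 24 h and -0.29 at 48 h), Pfkm (0.34 and -0.46) and Rb1 (-0.39 and 0.48).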

How the results depend on the processing

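The alternatives chosen only after seeing the data were the replicate block by column number, the protein-coding rescaling and leaving out Atf4 with its neighbours. No called result among the named genes and lists reversed its direction under any alternative that was run. The other called genes were not checked in this way. With size factors the larger share of all calls turned from rises to falls at 24 h, at 48 h and in the change of the difference. The same turn was seen from 0 to 12 h in both genotypes and from 12 to 24 h in KO. It was also seen among genes called at 2 or more times. The number of genes changed kept within 1.5 times the reported one for every comparison with a pseudocount of 0.1 or 5 (apart from 0 h), a filter of 5 FPKM, size factors, quantile normalisation and robust variance moderation, and at 48 h with the protein-coding rescaling. Without Atf4 and its neighbours 39, 3889 and 5842 genes changed at 12, 24 and 48 h.

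Without a filter, which adds lowly expressed genes to the adjustment, 19 genes changed at 12 h, 1188 in the change of the difference and 1006 at 2 or more times. With only the 4 libraries of a time point in the fit, 197 genes changed at 12 h and 2021 at 24 h, against 43 and 3891 in the joint fit. The joint fit gives each gene 1 spread over these times. The median absolute difference between the 2 libraries of a group was 0.166 on the log2 scale in WT at 24 h. It was 0.075 in WT and 0.08 in KO at 12 h, and 0.078 in KO at 24 h. The contrast between the counts at 12 and 24 h therefore depends in part on this pooling. Whether pooling alone moved the counts was not tested. At 0 h, 21 genes were at least 2-fold apart with a pseudocount of 0.1 and 7 with 5, as the pseudocount sets how far low genes can differ.

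Leaving out each library in turn, which removes 1 of the few degrees of freedom, gave 8 (without WT library 2) to 13 (without WT library 3) genes at 12 h and 1672 (without KO library 2) to 5326 (without WT library 3) at 24 h. At 48 h it gave 0 (without KO library 1, where limma had 4667 genes with an unadjusted p under 0.05) to 6006 (without WT library 1). From 12 to 24 h it gave 2796 (without WT 12 h library 2) to 5933 (without WT 24 h library 3) in WT, and 1870 (without KO 24 h library 2) to 2236 (without KO 24 h library 3) in KO. For the change of the difference it gave 291 (without WT 12 h library 3, or without KO 24 h library 2) to 4055 (without WT 24 h library 3). Of 1056 values of named genes in these runs, 830 kept their side of the threshold and 226 no longer passed. Of 824 list results, 790 kept theirs, 23 no longer passed and 11 passed only then.

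With the column number as a replicate block, 28 genes changed at 12 h, 3420 at 24 h, 5904 at 48 h, 4532 and 3725 from 12 to 24 h in WT and KO, and 1620 in the change of the difference. Psd (adjusted p = 0.154), Bub1b (0.0979), Eif4ebp1 (0.0787), E2f1 (0.0733) and Gpt2 (0.0629) then did not pass at 12 h, nor did Srxn1 (0.0613) at 24 h or Ccl3 (0.0604) in the change of the difference. The cause was not tested. Differences between the libraries with the lower and the higher number correlated across genes between WT and KO with r = 0.091 at 12 h, 0.163 at 24 h and 0.082 at 48 h. Between 12 and 24 h they correlated with r = 0.152 in WT and 0.403 in KO. The labels do not say what equal numbers share, and whether they tie libraries over time stays open. The block by the labels' numbers was not run because those could not be tied to columns, nor was the planned count test, since reads recovered from FPKM would need gene lengths that the files do not hold. Depth limits low genes most: at 0 h the libraries held an estimated 13 M and 11.7 M reads.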

Other observations

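The gene families of the next paragraph and the tests of a change in cis and of the activation response were chosen only after the result was seen, and those of paralogs, of unspliced RNA and of the summed receptor genes before it.

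Some of the families chosen after their values were seen leaned to 1 direction at 48 h. No list p value supports them because of that choice. Of 38 proteasome genes 36 fell, with a median of -0.56 on the log2 scale (-0.30 after quantile normalisation), as did 68 of 78 mitochondrial ribosomal protein genes (-0.48 and -0.42), all 7 chaperonin genes (-0.64 and -0.33) and 60 of 103 cytosolic ribosomal protein genes (-0.43 and -0.15), a family with 12 rises and 4 falls at 24 h. Of 13 mitochondrially encoded genes 11 rose, with a median of 0.48 (0.71 after quantile normalisation), and of 48 T cell receptor α joining segments 37 rose (1.64 and 1.25). Some others leaned less clearly at 48 h: of the Gimap genes 4 rose and 2 fell, of the kinesins 3 rose and 7 fell and of the small nucleolar RNAs 27 of 100 rose and 8 fell, and the median of the splicing genes went from -0.23 to -0.015 after quantile normalisation. None of the families passed with an estimated correlation, where the lowest adjusted p was 0.314.

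Cacna1i was higher and Rps19bp1 lower in KO at every time, and both lie within 150 kb of Atf4. Loss of a response to activation is argued against for Cacna1i, whose log2 difference at 0 h was 0.926 of that at 24 h. It may account for Rps19bp1, where this share was 0.23. Both shares rest on 1 library per genotype at 0 h. The 0 h difference of Cacna1i was 5.24 with a pseudocount of 0.1 and 1.962 with 5, so its size depends on the pseudocount. The tables also argue against reads shared with Cacna1g and Cacna1h, whose summed FPKM changed by at most 0.0435% of the rise of Cacna1i. A change in cis at the recombined locus stays open: 0.02% of windows of 5 consecutive tested genes elsewhere held 2 genes changed at all 3 times, but the locus was examined because its neighbours had changed, so this share lends no support. Loss of the basal ATF4 protein stays open too, as no test here separates it from the recombined DNA.

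Features annotated inside introns of other genes, such as Mir5123 and Mir7227, were higher in KO at 48 h: of 268 tested 105 rose and 8 fell, with a median of 0.68. Genomic DNA reads may contribute, since the summed FPKM of olfactory and vomeronasal receptor genes was 2.31 times higher in KO. Over 1487 such genes the sum was 4.94 and 3.47 FPKM in WT libraries 1 and 2. It was 11.4 and 8.09 in KO libraries 1 and 2. Receptor genes above 0 numbered 37 and 35 in WT libraries 1 and 2, and 134 and 76 in KO libraries 1 and 2. Each tested intron feature had a group mean of at least 1 FPKM because the filter required it. The low sums therefore cannot show how much of the rise came from genomic DNA. A higher share of unspliced RNA may also account for the pattern: the 100 intron features whose host gene fell had a median of 0.495. Their hosts had a median of -0.43, which is below 0 because only hosts that fell were selected. The features include microRNA and small nucleolar RNA genes, whose own levels were not separated from intron reads. Neither source was excluded as a contributor. Whether the rise lies in the cells or in the preparation of the 48 h libraries stays open. Whether it bears on the falls of spliced transcripts at 48 h stays open too. No batch or extraction date is given in the sources used here.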
